A study of Mus musculus with 2 samples.

How the data were processed

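Chromatin accessibility was measured by ATAC-seq in facial prominences pooled from 109 and 88 mouse embryos at 11.5 days, 1 library per pool, with Nextera tagmentation and fragments of 200 to 750 bp per the labels. The labels put both libraries in 1 group and call them biological replicates, so no comparison between conditions and no pairing was possible.

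Only the deposited peak lists were used. Each replicate had a ranked list, an IDR-thresholded list and a pseudoreplicated list, and the series had the same kinds made from both replicates together, with a conservative thresholded list and a replicated list besides, on the mouse assembly mm10 per the deposited text file. That text derives the thresholded, pseudoreplicated and replicated lists also from a further file whose content it does not state. The aligner, the peak caller, any shift of reads for the transposase and the software versions are not given in the sources used here. The signalValue of a peak is the authors' own score without a stated reference, and it was used only to describe, rank and select peaks and to correlate shared regions. The strength of each peak is also deposited as −log10 of its p-value, and the ranked lists carry −log10 of the global IDR, likewise a score as deposited. The files hold no read counts, so the depth of each library is unknown, no counting error could be given, and an absent region does not show that a site was closed. The pooled ranked lists hold 4 columns of values per replicate that were not used here.

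Overlapping peaks were merged into regions before counting, and the summit of the strongest peak stood for the region. Regions on the assembled chromosomes were used. The reference was GRCm38 with the basic GENCODE release M21 annotation, and every list's last peak lay inside its reference chromosome; the full GENCODE and RefSeq annotations served for further TSSs. A promoter region had its summit within 1 kb of the TSS of a transcript in the basic annotation, and the others were distal. Random placements, 100 per list, kept each region's length and chromosome and avoided assembly gaps. Regions were called shared at an overlap of 1 bp or more.

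The gene lists, motifs, loci, tests and most alternative settings were chosen before the data were examined. There were 17 lists: cranial neural crest mesenchyme, jaw and arch patterning, facial signalling, surface epithelium, placodal and neuronal, peripheral glia, skeletal muscle, endothelium, erythroid, macrophage, cartilage and bone matrix, Hox, cardiac muscle, hepatocyte, gut and pancreas, spermatogenesis and housekeeping. Of 311 genes written, 310 matched the annotation and 1, Ahsp, did not. A gene's promoter was open where a region of both replicates overlapped the 1 kb to either side of one of its TSSs. Promoter access compared each list with all other protein-coding genes, 21938 in all, by a two-sided Fisher's exact test. Distal regions within 50 kb of a gene's TSS, averaged over the replicates, were summarised by the list's median and compared with 10000 random lists of the same size matched on the number of protein-coding TSSs in the window; the smallest two-sided p these allow is 0.0002. Genes are not replicates, and both p-values describe these libraries. Loci were counted within 500 kb.

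For 38 motifs, the share of distal regions with a match within 100 bp of the summit was set over the share in windows of the same size centred 500 bp to each side and outside any region. A two-sided exact sign test used regions with a match in only one of the summit and 1 randomly drawn side window. A motif was called when both replicates passed 0.05 in the same direction and the mean ratio was above 1.25 or below 0.8, so a motif without any match in the side windows, such as NRF1, could not be called. All families of tests were adjusted by Benjamini-Hochberg.

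The genes named were set by a rule: in each list the 4 members with the most distal regions and 2 without a promoter region, the 10 genes with the most distal regions, the 5 strongest distal regions, the genes of the loci, and any member within its list's count. Gene families, transfer RNA genes and the sharing of sequence with mitochondrial DNA (an alignment of at least 100 bp at 90% identity) were chosen after the data were examined.

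Alternatives changed the list (pseudoreplicated, above the median signal, or pooled), the merging, the overlap, the windows, the background genes or sequences and the replicates used. The overlap, the exact promoter test, the distal median test, the motif test and the shuffle were tested on simulated data first, and the other procedures were not. Planted lists were open or closed throughout, or had regions added to every gene, and the simulated genes were independent. Recovery there does not carry over to the IDR-thresholded distal counts, whose median was 0 in every list, or to genes that share neighbourhoods. An overlap of 60.2% planted among 11315 regions was measured as 60.4%, 40 of 40 planted promoter calls and 5 of 5 planted distal calls over 21938 genes were recovered with 0 false calls, 1 of 1 planted motif was recovered in 2000 sequences with 0 false calls, and 200 of 200 shuffled sequences kept their dinucleotides. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and pysam 0.24.0, BLAST+ 2.17.0 and samtools 1.23.1.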

Results

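Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into DNA that nucleosomes leave exposed, in the facial prominences of mouse embryos at 11.5 days of development (E11.5). At this stage the maxillary, mandibular and nasal swellings consist mainly of cranial neural crest mesenchyme under a surface epithelium. Placodes, nerves, vessels, blood and the myogenic core of the arches lie within them. The series held 1 group of 2 biological replicates of the strain B6NCrl, pools of 109 and 88 embryos of both sexes. With 1 tissue and 1 stage there was no contrast between conditions. The comparisons were made among genes, regions and sequence motifs within this tissue. Values carry the spread between the 2 pools where given, and the tests ran over genes or regions of these libraries. The values were peak lists without read counts, so the depth of either library is unknown.

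Accessible regions of the facial prominence lay mostly at promoters. In the lists thresholded by irreproducible discovery rate (IDR), 11714.5 ± 565 regions (SD, n = 2) covered 10.9 Mb in each replicate. Of them, 79.7% ± 1.29 (SD, n = 2) had their summit within 1 kb of an annotated transcription start site (TSS), 17.5 ± 0.338 times the share of randomly placed regions. Introns held 9.26% ± 0.417 and intergenic DNA 9.69% ± 0.806, against 42.2% and 50.2% of random placements, while coding exons (0.573% ± 0.0397) and 3' UTRs (0.319% ± 0.0631) also lay below their random shares of 1.23%. The larger pseudoreplicated lists, with 33592 and 36599 regions, held more distal sequence, and 43.9% ± 2.42 (SD, n = 2) of their regions were at promoters, still 9.76 ± 0.496 times the random share. Coding exons turned there to 1.64% ± 0.045, above their random share of 1.22% (1.35 ± 0.0214 times). The pooled list of the series had 16369 regions, of which 69.6% were at promoters. No test was made over regions, which are not replicates; the promoter share exceeded the random share by far more than the spread between the pools in both kinds of list.

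**Figure D1:**
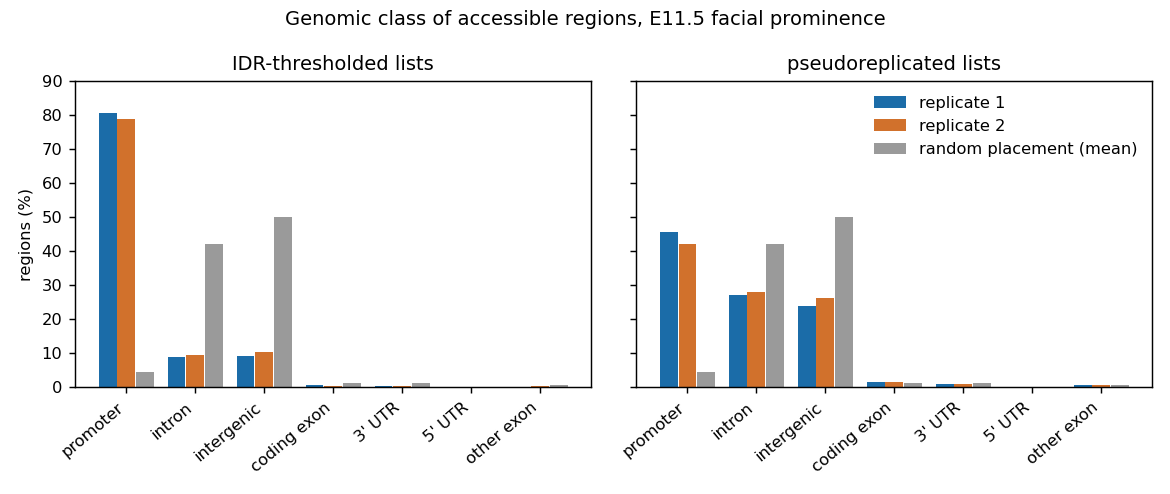
Share of accessible regions (vertical axis, percent) in each genomic class for replicate 1 (blue), replicate 2 (orange) and the mean of random placements (grey), for the IDR-thresholded lists (left) and the pseudoreplicated lists (right). Promoters took 79.7% of the IDR-thresholded and 43.9% of the pseudoreplicated regions on average over the replicates, against random means of 4.55% and 4.50%.

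Most promoter regions were found in both pools of embryos, and a smaller share of distal regions was. Of the 11315 regions of replicate 1, 86.0% overlapped a region of replicate 2, and of the 12114 regions of replicate 2, 80.7% overlapped one of replicate 1, against 0.902% by chance. Promoter regions were shared at 90.7% and 87.2%, distal regions at 66.2% and 56.6%. Sharing rose with strength, from 68.1% and 55.4% in the weakest of 4 equal groups of regions by signal to 99.5% and 99.1% in the strongest. Of the regions without a partner, 91.9% in replicate 1 and 92.1% in replicate 2 lay over a region of the other pool's pseudoreplicated list. Across the 9728 shared regions, which are not independent replicates, the authors' signalValue had a Spearman correlation of 0.847 and a Pearson correlation of 0.851 on the log10 scale, and 97.9% of regions were within 1.5-fold.

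**Figure D2:**
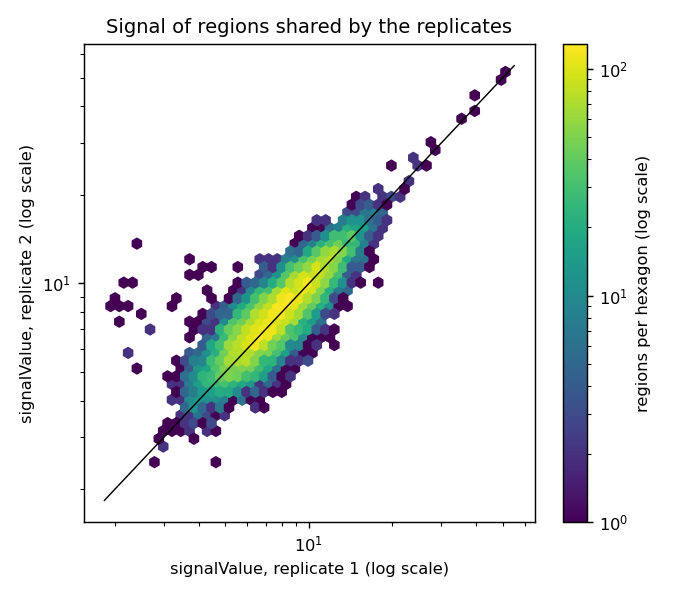
The authors' signalValue (a score without unit, log scales) of the 9728 regions shared by the replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, with colour giving the number of regions per hexagon on a log scale and the line marking equal values. The values followed the line with a Spearman correlation of 0.847 across regions.

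Most housekeeping genes had an open promoter, no Hox gene and few markers of blood, muscle, liver and gut had one, and the shares of the facial lists lay between them. A promoter counted as open where both replicates had an IDR-thresholded region within 1 kb of a TSS, which held for 8771 of 21938 protein-coding genes. Of the housekeeping genes, 14 of 16 were open (exact test, adjusted p = 0.00071). SignalValues were 12.8 ± 0.392 at Eef1a1, a translation elongation factor, and 10.3 ± 0.945 at Rplp0, a ribosomal protein. None of the 39 Hox genes, which pattern the trunk and the posterior arches, was open (exact test, adjusted p = 6.1e-08), and 4 of their promoters have a further copy in the genome. By the same exact test, neither were any of the 19 hepatocyte genes (adjusted p = 0.000614), 16 skeletal muscle genes (adjusted p = 0.00173), 15 macrophage genes (adjusted p = 0.00254) or 13 erythroid genes (adjusted p = 0.00741). By the exact test, few promoters were open in the lists of cartilage and bone matrix (1 of 16, adjusted p = 0.0103), gut and pancreas (1 of 15, adjusted p = 0.0151), surface epithelium (2 of 19, adjusted p = 0.0161) and endothelium (1 of 14, adjusted p = 0.0204). These 10 of 17 lists passed the threshold of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists). The 39 Hox genes lie in 4 clusters. The exact and permutation tests, here and below, treat them as independent genes, so the p-values of Hox overstate the evidence.

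The 3 facial lists and the placodal and neuronal list did not pass this test. Among the cranial neural crest mesenchyme genes 10 of 24 promoters were open (exact test, adjusted p = 0.891). Open were Ets1 (signalValue 10.6 ± 0.415), Six2 (9.60 ± 0.269) and Snai2 (8.66 ± 0.672), a repressor of the epithelial state in migrating crest. So were Twist1 (6.67 ± 0.224), a basic helix-loop-helix factor of head mesenchyme, and Sox9 (5.33 ± 0.895), the chondrogenic SOX factor. In jaw and arch patterning 6 of 22 were open (exact test, adjusted p = 0.339). They were Pax9 (7.91 ± 0.176), needed for teeth and palate, the endothelin receptor gene Ednra (6.31 ± 0.262), Dlx1 (5.97 ± 0.450), Pou3f3, Six1 and Satb2. By contrast, Hand1, Lhx8, Edn1 and Pitx1 had no promoter region in either replicate. In facial signalling 8 of 23 were open (exact test, adjusted p = 0.765), with Spry2 (8.82 ± 1.09) and Gli3 (8.23 ± 1.78) the strongest. Shh, Fgf8 and Wnt3, ligands of the facial epithelium, had none. In the placodal and neuronal list 7 of 18 were open (exact test, adjusted p = 1), led by Elavl4 (9.67 ± 0.0259), Isl1 (8.19 ± 1.11) and Foxg1 (8.13 ± 0.496). The counts of peripheral glia (1 of 9, adjusted p = 0.125, exact test), cardiac muscle (2 of 16, adjusted p = 0.053) and spermatogenesis (2 of 16, adjusted p = 0.053) did not pass either. Their open members were Mpz, a myelin gene, Actn2 and Tbx20, and Zpbp and Dazl.

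The open members of the lists with few open promoters were Pitx2 (8.82 ± 0.595) and Irf6 (7.20 ± 1.12) in surface epithelium, both transcription factors of the oral epithelium. Elsewhere they were Nkx6-1 (8.71 ± 0.751) in gut and pancreas, a homeodomain factor also known in neurons, Col9a1 (7.39 ± 0.0952) in cartilage and bone matrix and Kdr (6.61 ± 2.12), a VEGF receptor gene, in endothelium. The share of open promoters rose with their CpG content, from 2.32% of genes in the lowest decile to 76.8% in the highest. Against random lists matched on that content 5 lists passed by a permutation test: Hox (adjusted p = 0.0034), surface epithelium (0.0068) and skeletal muscle (0.0159) lower, jaw and arch patterning lower (0.0483) and housekeeping higher (0.0483). Endothelium (0.102), erythroid (0.229), macrophage (0.556), cartilage and bone matrix (0.127), hepatocyte (0.314) and gut and pancreas (0.0516) did not. Each of them still lay below its matched share, from 0% against 8.50% in macrophage to 6.67% against 32.7% in gut and pancreas. With only regions above the median signal, Hox alone passed.

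**Figure D3:**
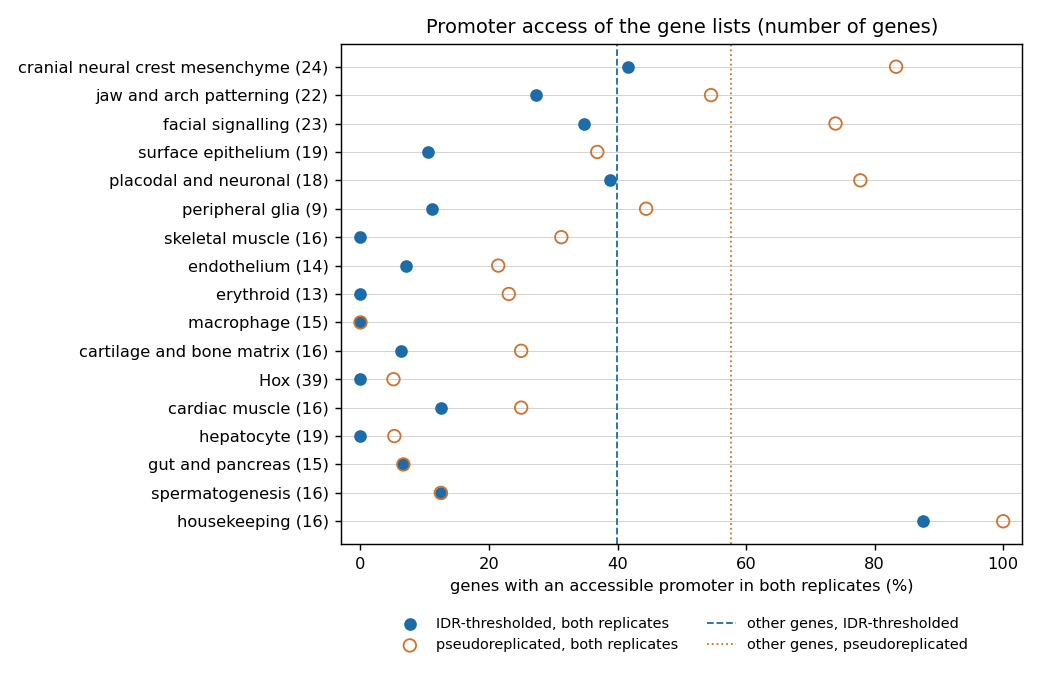
Percent of the genes of each list (horizontal axis; number of genes in parentheses) with an accessible promoter in both replicates, in the IDR-thresholded (filled blue) and the pseudoreplicated lists (open orange), with vertical lines at the share of other genes. Hox lay at 0 and 5.13%, housekeeping at 87.5% and 100%, and cranial neural crest mesenchyme at 41.7% and 83.3%.

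In the pseudoreplicated lists, which reach weaker regions, most promoters of the facial mesenchyme list were open and those of Hox genes were not. Cranial neural crest mesenchyme had 20 of 24 promoters open (exact test, adjusted p = 0.0201), now with Foxc1, Msx2, Runx2, Osr1, Tfap2a, Prrx1 and Alx3. Of random genes of the same CpG content 72.9% were open (permutation test, adjusted p = 0.280). Of the Hox genes 2 of 39 were open (exact test, adjusted p = 6.8e-11), Hoxa1 (signalValue 4.48 ± 0.622) and Hoxc13 (3.68 ± 0.0518). In genes of the same CpG content 79.4% were open (permutation test, adjusted p = 0.0017). Housekeeping reached 16 of 16 (exact test, adjusted p = 0.000582; matched on CpG, 0.0306). Macrophage (0 of 15), hepatocyte (1 of 19), gut and pancreas (1 of 15), spermatogenesis (2 of 16), endothelium (3 of 14), erythroid (3 of 13), cartilage and bone matrix (4 of 16) and cardiac muscle (4 of 16) were lower than other genes, with exact adjusted p from 1.4e-05 to 0.0319. Against random lists matched on CpG content, 6 of these 8 calls were lost, and those of gut and pancreas (permutation adjusted p = 0.0017) and spermatogenesis (0.00935) were kept. Among the lost calls, endothelium had 21.4% open against 50.6% in matched genes and erythroid 23.1% against 24.2%, and the others also lay below their matched shares. Facial signalling (17 of 23), placodal and neuronal (14 of 18), jaw and arch patterning (12 of 22), surface epithelium (7 of 19), skeletal muscle (5 of 16) and peripheral glia (4 of 9) did not pass, with adjusted p from 0.0594 to 0.831 by the exact test. Of these, 2 were called lower against random genes of the same CpG content, jaw and arch patterning (54.5% against 77.2%, permutation adjusted p = 0.0306) and surface epithelium (36.8% against 69.9%, 0.00907). In all, 12639 of 21938 genes (57.6%) were open in both replicates of these lists.

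Distal regions near the facial genes were too sparse in the IDR-thresholded lists for the test to separate any list. The median number of distal regions within 50 kb of the TSS was 0 in each of the 17 lists, and 0 lists passed, with 0 at an unadjusted permutation p under 0.05. Among single genes, Fgfr1, a fibroblast growth factor receptor gene, had 3.5 such regions (mean of the replicates), Hand2, a regulator of the lower jaw, had 2, and Nr2f1 and Ptch1, the latter the receptor of Shh, had 1.5 each. Members of other lists had as many as Hand2 but fewer than Fgfr1. Tnni3 (cardiac muscle), Vil1 (gut and pancreas), Col2a1 (cartilage and bone matrix) and Mpz (peripheral glia) had 2 each, and the strongest region near Tnni3 reached 10.4 ± 0.876. In mm10 coordinates, the strongest region near Hand2 lay in an annotated intron at 8:57353432–57354269, 32.8 kb downstream of its TSS, with a signalValue of 7.97 ± 1.59 (SD, n = 2). That of Nr2f1 lay outside the gene, in an intron of another annotated gene at 13:78162996–78164033, 36.6 kb downstream, with 7.69 ± 1.53. Within Fgfr1 the strongest was an intronic region at 8:25543138–25543860 with 7.57 ± 1.38.

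In the pseudoreplicated lists, genes of the face, its placodes and skeletal muscle had more distal regions than random genes of like gene density. By a permutation test, the median was 2.75 regions per gene in cranial neural crest mesenchyme (adjusted p = 0.0017) and 2.5 in placodal and neuronal genes (adjusted p = 0.0017). In the same permutation test it was 2 in jaw and arch patterning (adjusted p = 0.00227), 2 in facial signalling (adjusted p = 0.00595) and 2 in skeletal muscle (adjusted p = 0.0109), against random means of 0.52 to 0.556. The smallest unadjusted p that the random lists can give, 0.0002, was reached by the neural crest and the placodal lists. Leading members were Ets1 (5 regions), Six2, Nr2f2 and Prrx2 (4.5 each) and Foxc1 and Snai1 (4 each) in the mesenchyme. In arch patterning they were Dlx4 (4.5) and Gsc (4), and in signalling Jag1 (6), Fgfr1 and Gli2 (4.5 each). Placodal and muscle genes with many were Neurog1 (6), Pax6 and Elavl3 (4.5 each), Pax7 (5) and Chrna1 (4). Genes of these lists could also have none, as Runx2, Pitx1, Edn1, Tbx22, Lef1, Aldh1a2, Eya1 and Ttn did. The call of skeletal muscle was lost in either replicate alone, with adjusted permutation p of 0.0947 and 0.053, and the other 4 held in both. Of the pseudoreplicated distal regions, 52.4% in replicate 1 and 45.4% in replicate 2 were shared, so the counts include regions of a single pool. The random genes came from all protein-coding genes outside the list, among them olfactory receptor genes with a mean of 0.165 such regions. List members that lie close together count the same regions, and the random lists were matched on gene density only. The permutation p-values treat such members as independent and may overstate the evidence.

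The remaining 12 lists did not pass by their medians in the pseudoreplicated lists. Their medians were 1.75 in endothelium and housekeeping and 1.5 in surface epithelium, erythroid, macrophage, cartilage and bone matrix, cardiac muscle and hepatocyte. They were 1 in peripheral glia and in gut and pancreas, 0.75 in spermatogenesis and 0.5 in Hox, with adjusted permutation p from 0.0618 to 0.882. In every list but Hox the median lay above the mean of its random lists, so a higher median was not particular to the face. Some of their members stood beside many regions all the same, such as Comp (6), a cartilage matrix gene, and Sp7 (5.5), an osteoblast factor. Others were Krt18 (5.5) and Krt8 (5), keratins of simple epithelia with 1 neighbourhood in common, Fli1 (5.5), an endothelial ETS factor, Ambp (5.5), and Mpz and Ngfr (5 each). Some of the regions near Mpz lay over transfer RNA genes. The strongest region counted for Fli1 lay 0.197 kb upstream of the gene's own TSS, where the basic annotation has no transcript start. Distal counts can thus include promoters. A region distal by its summit could also overlap a promoter window, as the strongest counted for Nr2f2 (7:70361347–70362377) did. Of the IDR-thresholded distal regions, 23.3% in replicate 1 and 21.8% in replicate 2 lay near a TSS of the fuller annotations. The counts near genes were not repeated without such regions. By the mean in place of the median, 6 of the 12 passed. By this permutation test cartilage and bone matrix (2.03 regions, adjusted p = 0.00952), surface epithelium (1.87, 0.0189), housekeeping (2.03, 0.0246), peripheral glia (2.11, 0.042) and endothelium (1.86, 0.042) were higher, and Hox was lower (0.718, 0.0264).

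**Figure D4:**
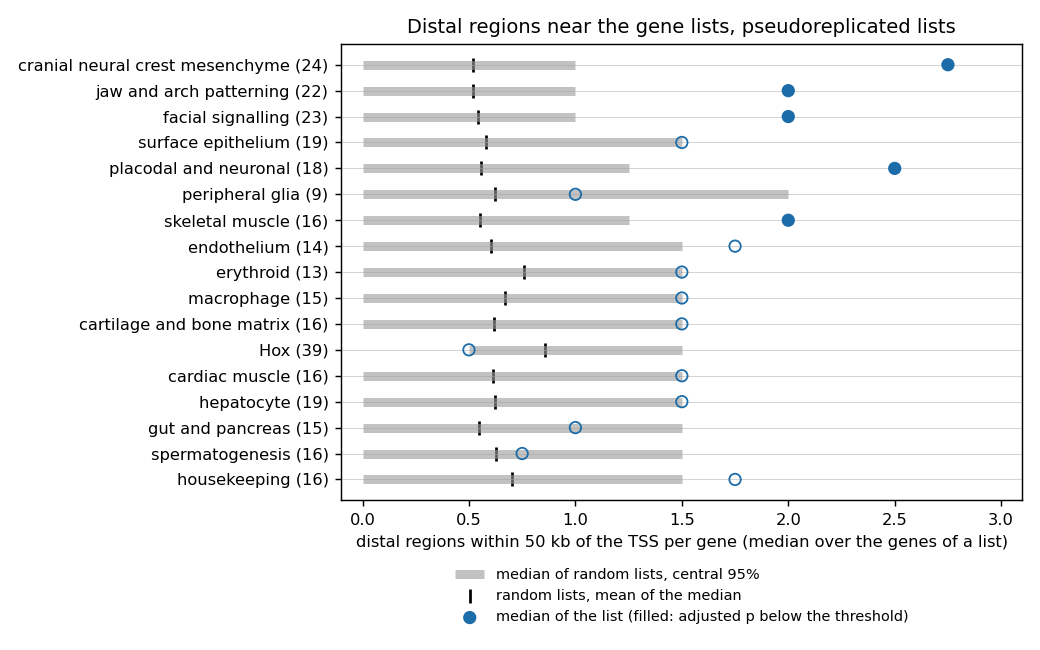
Median number of distal regions within 50 kb of the TSS per gene (horizontal axis) for each list in the pseudoreplicated lists (circles, filled where the adjusted p was below 0.05), with the central 95% of random lists of the same size and gene density (grey bars) and their mean (ticks). Filled circles mark cranial neural crest mesenchyme at 2.75, placodal and neuronal genes at 2.5, and jaw and arch patterning, facial signalling and skeletal muscle at 2.

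Wide neighbourhoods of the facial genes held no more distal regions, in the median, than those of genes in general. Within 500 kb of the TSS the 14 facial loci had a median of 0.5 IDR-thresholded distal regions, against 1 over all protein-coding genes, and of 9 pseudoreplicated regions, against 9.5. The fullest of them were Pitx1 and Six1, with 17.5 ± 3.54 pseudoreplicated regions each (SD, n = 2; percentile 84.4 of genes). Next came Sox9 with 15.5 ± 0.707 (78.0), Pax9 with 14.5 ± 3.54 (73.9) and Msx1 with 13.5 ± 3.54 (69.7). Satb2 (9.5 ± 3.54), Hand2 (9 ± 1.41), Alx1 (9 ± 2.83), Twist1 (8 ± 2.83) and Bmp4 (7.5 ± 2.12) were near the middle. Shh (5.5 ± 2.12), Dlx5 (5 ± 1.41), Tfap2a (3.5 ± 0.707) and Myc (2.5 ± 2.12) lay below it. Of the loci chosen for other cell types, the heart regulator Nkx2-5 had 18 ± 0 and the muscle regulator Myod1 14 ± 4.24, whereas the liver gene Alb had 2.5 ± 2.12 and the embryonic globin gene Hbb-y 0.5 ± 0.707. In the IDR-thresholded lists Sox9 had 3 ± 0, Hand2 2 ± 0 and Pitx1 4 and 0 in the replicates. No test was made for single loci, and the ranking among genes was not matched on gene density, unlike the test within 50 kb.

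Summits of distal regions carried motifs of CTCF, of promoter-type factors and of E-box and TFAP2 factors, and few TAAT or GATA motifs relative to the DNA beside them. CTCF motifs, the binding sites of the insulator protein, were in 4.02% ± 0.0636 of summits (SD, n = 2), 31.3 ± 18.9 times the share of side windows (17.9 in replicate 1 and 44.7 in replicate 2). Ratios were 14.3 ± 11.2 for CREB (22.2 and 6.31 in the replicates), 12.5 ± 1.51 for RFX, a factor of ciliated and other cells, 9.11 ± 1.09 for NFY, 6.48 ± 0.15 for ETS, 5.91 ± 0.193 for SP-KLF and 4.28 ± 0.475 for ZIC. The TFAP2 motif, bound by regulators of neural crest and surface ectoderm, was in 13.9% ± 0.404 of summits (ratio 3.07 ± 0.0107). The E-box CAGCTG was in 24.4% ± 1.65 (2.67 ± 0.393) and the TWIST-type E-box CATCTG in 18.6% ± 0.659 (1.27 ± 0.0425). Lower at summits were the homeodomain motif TAATTA, shared by ALX, DLX, MSX and LHX factors (0.603 ± 0.0216), GATA (0.336 ± 0.0222) and IRF (0.296 ± 0.0802).

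These 13 of 38 motifs were called because both replicates passed in the same direction, by an exact two-sided sign test over regions with Benjamini-Hochberg adjustment. The least certain calls by the exact test were ETS (adjusted p of 0.000304 and 5.3e-05) and TWIST-type E-box (0.016 and 0.00149) among those higher and TAATTA (0.00452 and 0.000111) among those lower. The combined E-box and homeodomain motif known as Coordinator, a mark of facial enhancers, was in 0.152% ± 0.0916 of summits with a ratio of 0.868 ± 0.394 and was not called. The motifs of SOX (1.04 ± 0.000367), FOX (0.816 ± 0.122) and TEAD (1.10 ± 0.0173) were not called either. Against summit sequences shuffled with their dinucleotides kept, TAATTA turned to a ratio of 4.71 ± 1.47 and was called higher. There TFAP2 had 1.00 ± 0.0572 and was not called, and GATA, IRF and ZIC were not called. Called higher there, unlike against side windows, were FOX (2.61 ± 0.0109), SOX (1.35 ± 0.136) and the motif bound by Six1 and Six2 (14.3 ± 5.30). The last ratio rests on very few matches, 0.0542% of shuffled sequences in replicate 1 and 0.0874% in replicate 2. In the pseudoreplicated lists 21 motifs were called, adding REST (20.4 ± 3.55), NFI (6.75 ± 0.0817), PBX-MEIS (3.77 ± 0.431), the motif bound by Six1 and Six2 (2.03 ± 0.297), MEIS (1.27 ± 0.0376) and TEAD (1.26 ± 0.00119) as higher. REST was in only 0.0915% ± 0.0401 of summits and NFI in 0.0804% ± 0.0168, against 0.00473% and 0.0119% of side windows. Their ratios thus rest on very few matches. Added as lower were PBX-HOX (0.457 ± 0.00342) and the paired-type homeodomain dimer (0.436 ± 0.154). The Coordinator motif had 0.690 ± 0.0499 there and was not called. Against shuffled summits of the pseudoreplicated lists 20 motifs were called, 0 of them lower. PBX-HOX turned to 1.75 ± 0.183 and IRF to 2.45 ± 0.394, and both were called higher. The paired-type dimer (2.06 ± 0.0337), NFI (6.86 ± 7.26) and MEIS (1.06 ± 0.0444) were not called. PBX-MEIS, TEAD and the motif bound by Six1 and Six2 were still called higher, and REST lacked a ratio.

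**Figure D5:**
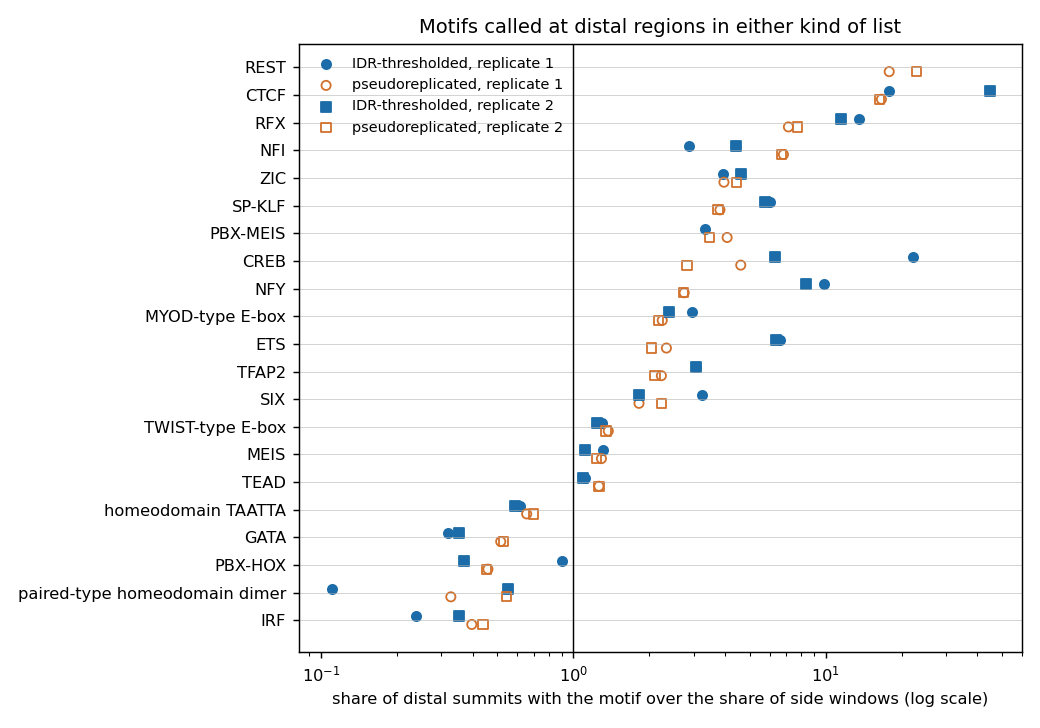
Ratio of the share of distal summits with a motif to the share of side windows (horizontal axis, log scale) for motifs called in either kind of list, in the IDR-thresholded (filled blue) and pseudoreplicated lists (open orange), circles for replicate 1 and squares for replicate 2; a replicate without a match in its side windows has no point. In the IDR-thresholded lists CTCF averaged 31.3 and GATA 0.336.

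The strongest distal regions had nearest genes outside the facial lists. By mean signalValue over the replicates they were, in mm10 coordinates, X:143482937–143483180, intergenic and 35.5 kb from Pak3 (51.7 ± 0.851, SD, n = 2), and 2:69355470–69355735, intergenic and 13 kb from Abcb11 (49.8 ± 0.259). They were followed by 10:96077549–96077951, in an intron and 58.9 kb from Gm5426 (41.0 ± 2.62), 2:3964425–3964689, intergenic and 53.2 kb from Frmd4a (38.8 ± 0.891), and 5:60042765–60043138, intergenic and 1766 kb from G6pd2 (36.7 ± 1.23). Of these 5, those on chromosomes 10 and 5 and the one near Abcb11 align to the mitochondrial genome. The one near Pak3 has 6 further copies in the nuclear genome. The genes with the most IDR-thresholded distal regions within 50 kb were Gm21860 on chromosome Y (5.5), Fcgr3 (5), Klrb1c (5), Actg1, Atf7ip, Cox4i2, Pcdhgc3 and Tle6 (4 each), and Fam213b and Fgfr1 (3.5 each). Klrb1c had 3 in replicate 1 and 7 in replicate 2. Chromosome Y held 7 regions in each replicate, and those near Gm21860 were 6 of them in replicate 1 and 5 in replicate 2. Fcgr3, an immunoglobulin receptor gene of myeloid cells, has 25 transfer RNA genes in its window, and 4 of its 4 regions in replicate 1 and 5 of its 6 in replicate 2 lay over them. Fgfr1 was the sole member of the 17 lists among these 10 genes.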

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

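The tests of mitochondrial sequence, base composition, CpG content and the list threshold as explanations were chosen only after the results were seen, although the comparisons with shuffled summits, genes matched on CpG and pseudoreplicated lists were themselves set before. The ranked list of each replicate, outside the comparisons made here, held regions that reached the IDR threshold of 0.05 and are missing from its thresholded list, 57 on the chromosomes in replicate 1 and 62 in replicate 2. Their highest −log10 p was 4629 and 5334, and 1 in each replicate aligned to the mitochondrial genome. Why they were left out is unknown: the further file behind the thresholded lists is not described, and neither they nor the strongest distal regions were compared with a list of artifact-prone regions, since none was given.

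The strongest distal regions, such as those near Abcb11 and Pak3, stood far above the regions near facial genes in signalValue. Of the 10 strongest, 5 align to the mitochondrial genome over 129 to 365 bp at 95.5% to 100% identity, against 1 of 1423 other shared distal regions (Fisher's exact p = 3.0e-11), so reads of mitochondrial DNA placed at nuclear copies are a candidate explanation for these. Of the 5 others, 4 have a further nuclear copy, against 13 of 100 drawn from the rest (exact p = 0.00223), so shared reads may add to their signal, and the region near Frmd4a has 0 such copies. The reads were not analysed here, and no biological explanation was tested because the series has 1 group.

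Motifs known from promoters, SP-KLF, NFY, ETS and CREB, were enriched at distal summits. Promoters outside the annotation are argued against as the whole cause: 23.3% and 21.8% of distal regions lay near a further TSS, and without them all 4 motifs were still called, with ratios of 5.79 ± 0.174, 7.74 ± 0.320, 5.01 ± 0.881 and 17.7 ± 14.3. Base composition is likewise argued against as the whole cause, since all 4 were called against shuffled summits, with ratios of 2.84 ± 0.374, 4.15 ± 0.453, 4.04 ± 1.64 and 30.5 ± 0.707. For SP-KLF, NFY and ETS these were below the ratios of 5.91, 9.11 and 6.48 against side windows, so composition may account for a part. For CREB the shuffled share rests on very few matches, 0.0542% of sequences in replicate 1 and 0.0437% in replicate 2. Its ratio, whose SD is no measure of precision, thus cannot be compared with that against side windows (14.3). Promoters absent from the fuller annotations as well, and promoter-like enhancers, stay open, and no biological explanation was tested.

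No Hox promoter had an IDR-thresholded region in both replicates, and the 4 clusters held 0 such regions in either replicate. Low CpG content is argued against, since 54.9% of random genes of the same CpG content were open, and so is the strict threshold, since 5.13% of Hox promoters were open in the pseudoreplicated lists against 57.7% of other genes. Sequence shared between paralogs cannot be told apart for the 4 of 39 promoters with a further copy of 100 bp or more at 90% identity, and the other 35 have no such copy. No biological explanation was tested because the series has 1 tissue.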

How the results depend on the processing

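The settings with a mean in place of a median, with each pseudoreplicated list alone, with matching on CpG in the pseudoreplicated lists, with side windows farther away and without mitochondrial-like or transfer RNA regions were chosen only after the results were seen. The depth of the libraries is unknown and limits all counts of regions. No paired analysis was possible because the series holds 1 group. Leaving out either replicate gave 11315 to 12114 regions, 78.8% to 80.6% at promoters, 11 to 12 promoter lists called, a median of 0 to 1 regions at the loci and 14 to 15 motifs called. The 0 distal lists called without either replicate say nothing about stability, because the median was 0 in all 17 lists to begin with. Unmerged, the lists had 30054.5 peaks on average. With the pseudoreplicated lists there were 35095.5 regions, 66.6% shared, a Spearman correlation of 0.820, 43.9% at promoters, 5 distal lists called, a median of 9 regions at the facial loci and 21 motifs called; these lists reach weaker regions by construction. Summits within 100 bp were shared at 70.5%, and the rank of −log10 p correlated at 0.868. Promoters took 76.2% at 500 bp, 82.1% at 2 kb and 89.3% above the median signal, where 1 promoter list and 7 motifs were called on fewer regions. Matching on CpG gave 5 promoter lists, with 4 calls kept, 6 lost and jaw and arch patterning gained. For the pseudoreplicated lists it gave 6, with 4 kept, 7 lost and 2 gained, jaw and arch patterning and surface epithelium. Distal lists called were 1 with the nearest TSS, 4 with the pooled list of the series and 1 (Hox, lower) with the mean. In the pseudoreplicated lists they were 11 with the mean, housekeeping among them, 5 with matching on CpG, 4 in each replicate alone and 5 without mitochondrial-like and transfer RNA regions. Against shuffled summits, among motifs called with either background, the ratios turned for TAATTA (4.71), FOX (2.61) and IRF (1.80), the first 2 called higher. TFAP2 lost its call at 1.00, and 8 of the 12 motifs called were also called in that direction against side windows. Of the single lists, 9 promoter calls were lost above the median signal and 2 were gained at 2 kb, and 0 changed at 500 bp. Of the 13 motif calls, 9 were kept with 50 bp windows, where CTCF lacked a ratio, and 11 with side windows at 2 kb. NR2F, REST, NRF1, HNF1, PBX-MEIS, OCT4-SOX2 and the SOX dimer lacked a ratio in 1 or both replicates, where the side windows held no match, and were not compared. The cause was not tested for the changes with the nearest TSS, the pooled list, the mean and the shuffled background.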

Other observations

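All tests in this part were chosen only after the results were seen. Sensory receptor families and genes of hair and drug metabolism had few accessible promoters, and families of genes used in every cell had many. In the pseudoreplicated lists of both replicates, 2 of 1135 olfactory receptor genes (0.176%) and 1 of 329 vomeronasal receptor genes had an accessible promoter. The keratin-associated proteins of hair had 0 of 57 (exact test, adjusted p = 1.9e-21) and cytochrome P450 20 of 100 (adjusted p = 3.5e-14). The clustered gamma protocadherins, adhesion molecules of neurons, had 2 of 21 (exact test, adjusted p = 9.2e-06). Cytosolic ribosomal proteins had 76 of 79 (exact test, adjusted p = 1.2e-14), mitochondrial ribosomal proteins 76 of 78 (adjusted p = 1.6e-15) and proteasome subunits 38 of 40 (adjusted p = 2.5e-07). Histones of the large cluster on chromosome 13 had 50 of 54 (exact test, adjusted p = 3.0e-08) and Zfp zinc fingers 308 of 365 (adjusted p = 1.2e-27). Dlx (4 of 6, adjusted p = 1, exact test), Fox (24 of 44, adjusted p = 0.875), Sox (12 of 19, adjusted p = 0.875), Wnt (9 of 19, adjusted p = 0.499) and Fgf genes (14 of 22, adjusted p = 0.836) did not pass Fisher's exact test with Benjamini-Hochberg adjustment over 15 families. In the IDR-thresholded lists Wnt genes had 0 of 19 (exact test, adjusted p = 0.000108), whereas Dlx (1 of 6), Fox (16 of 44), Sox (5 of 19) and Fgf genes (5 of 22) did not pass, with exact adjusted p from 0.159 to 0.758. The other 10 families passed in the same direction in both kinds of list. The exact test treats genes as independent. The gamma protocadherins and these histones lie in clusters, so their p-values overstate the evidence. The same holds for any other family whose members lie side by side. These tests were not matched on CpG content. In the pseudoreplicated lists 4.38% of promoters were open in the lowest CpG decile and 95.8% in the highest. Sequence shared between members of a family was not examined either, so neither was separated from the family differences.

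Transfer RNA genes, transcribed by RNA polymerase III, lay under a region of both replicates in 70 of 403 cases (17.4%) in the IDR-thresholded and 137 (34.0%) in the pseudoreplicated lists. By chromosome, 11 (6.68 regions per Mb), 17 (5.95) and 7 (5.81) were densest in the IDR-thresholded lists. Chromosome X had 2.31 regions per Mb at 5.54 protein-coding genes per Mb, and chromosomes 18 and 12, with 5.66 and 5.35 genes per Mb, had 3.69 and 3.8. The pools held embryos of both sexes. No test of the X was made.

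A hypothesis was that transcription factor genes of an organ carry more distal regions than its other markers. With the pseudoreplicated lists, for the skeletal muscle, cardiac, hepatocyte and gut genes, the 22 factors had 1.75 ± 1.09 and the 44 other genes 1.39 ± 1.28, a difference of 0.364 (SD over genes, permutation p = 0.241), which leaves it open. Genes are not independent replicates, and neighbours share regions. Skeletal muscle was included although the myogenic core of the arches lies within the tissue, so not all of these genes belong to organs absent from it.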
